A study of Arabidopsis thaliana with 6 samples.

How the data were processed

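Total RNA from rosette leaves of 5-week-old plants, grown under 15 h of light and 9 h of dark, was extracted with TRIZOL, and 10 µg were turned into biotin-labelled target for an Affymetrix array, per the labels' protocols. The plants received no treatment. RMA, a method of background correction, quantile normalization and probe summary, is named in the submitters' processing notes with no version. The deposited values are intensities on a linear scale, 1 per probe set and array, all above 0. RMA output is on the log2 scale, and the notes used here do not say how these deposited intensities came to be linear. The median intensity per array was 42.1 to 43.7 in Col-0 and 49.0 to 50.15 in OH1, so the arrays were close in distribution and not identical. Detection calls and scanner files were not used here, so dim probe sets could not be told from background. The number of arrays sets the precision.

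For the tests the log2 of each intensity was taken with no offset. The 64 control probe sets were left out, and 22746 probe sets were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, as OH1 minus Col-0 over all 6 arrays with no covariate. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets. A probe set was called at an adjusted p below 0.05. Changes are given as log2 with the model's SE or as fold changes of geometric means, and levels as the mean ± SD of the linear intensities of 3 arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

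Probe sets were named from the platform annotation and its gene identifiers. Of the 22746 probe sets 13513 name 1 gene, 503 name several and 8730 have no name in the table used here, which does not mean that they have no gene. By gene identifier, 13436 of the 1-gene probe sets matched the reference gene table of assembly TAIR10.1, which gave the symbols, and 13356 genes had at least 1 probe set of their own. The probe table names 68.2% of the protein-coding genes known by a locus code alone and 15.5% of those with a symbol, so well-studied genes are thinly covered. LecRK-VI.2, the other clade VI genes, FRK1, PR1 and RD29A are among those not analysed here. Related genes can share probes, so a member of a tandem family can carry signal of its neighbours. The build behind the probe design is not given in the sources used here, and the reference served only for names and for which genes neighbour each other.

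Before the data were examined, 27 gene lists by locus, with 474 entries, and 13 families by symbol were fixed, together with the tests and the alternatives. Only 57 of the 474 entries were measured, and 8 lists had the 5 measured members needed for a test. Because of this thin coverage, 24 further lists were compiled, along with every symbol stem shared by at least 5 measured genes. The plastid genome list came from the plastid chromosome. In the other further lists, such as the salicylic acid-associated and flagellin-responsive loci, genes were assigned by locus from background knowledge. No source is cited for these assignments, and list membership remains to be checked. The further lists and the stems were drawn up with the gene names in view and before any comparison between the genotypes was computed. Each gene was represented by its brightest probe set. Lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted within the 8 lists fixed beforehand and within the 63 later ones (42 symbol stems and 21 others). The plan had named a single adjustment over all lists tested. That adjustment gives 0.0459 for the WRKY genes, 0.0182 for the alpha-expansins and 0.0183 for the glutathione transferases, and moves no list across 0.05. Camera with an estimated correlation and fry were alternatives. The rule for named genes began with called probe sets that name 1 gene, with all OH1 arrays on one side of all Col-0 arrays. Of these it took the 15 largest rises and the 15 largest falls, 1 probe set per gene. Only 1509 of the 3004 probe sets called at least 2-fold name 1 gene, so larger changes may lie among the others. The rule also took up to 4 called members of each list (or 2 uncalled ones where none was called) and 5 fixed markers. Last came the 2 nearest measured genes on each side of the LecRK-VI.2 locus. The rule gave 176 genes, of which those most informative for each group are named. Genes named outside the 176 are of 2 kinds. Some are uncalled members of lists fixed beforehand, given beside the called ones to complete the list. The others are marked in the text as named or picked out after their values were seen.

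The fit was tested on simulated data with 200 of 22746 probe sets changed in the OH1 arrays. It recovered 85% of log2 changes of 1 and 99% of log2 changes of 2, with 13 unchanged probe sets called (6.6% of the calls). The simulated noise was equal in both groups, while the median SD in the data was 0.139 in Col-0 and 0.181 in OH1. In the data 33% of the probe sets were called, far more than were changed in the simulation. The 85% and the 6.6% are therefore not the power and the false share of the real calls. On simulated lists with no shift, camera gave a p below 0.05 for 3% of 200 lists, and a shifted list was found. The simulated noise was independent between genes, so the 3% is no error rate for lists of correlated genes. The estimated correlation in the data was 0.65 for the salicylic acid-associated loci and 0.73 for the plastid genome.

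Alternatives covered quantile normalization, centring of arrays on the median or the 75th percentile, leaving out the dimmest 40% of probe sets, eBayes with a trend, robust eBayes, array weights, the replicate number as a block, log2 after adding 32, other thresholds, 1 probe set per gene, averaged probe sets of a gene, and each array left out in turn. Where an array was left out, limma's pooled spread was used with 2 arrays in that group.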

Results

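Rosette leaves of untreated 5-week-old Arabidopsis plants were profiled on 6 arrays, 3 from wild-type Col-0 and 3 from OH1, a transgenic line in the Col-0 background that over-expresses the lectin receptor-like kinase gene LecRK-VI.2. L-type lectin receptor kinases carry an extracellular lectin domain and an intracellular kinase domain, and LecRK-VI.2 is known for its role in immunity triggered by microbial patterns. The comparison asks how the leaf transcriptome of the over-expressing line differs from that of the wild type when no pathogen or elicitor is applied. Each array gave an intensity for 22810 probe sets, of which 22746 were tested and 64 were control probe sets. The labels call the arrays of a group biological replicates. The number of arrays, 3 per group, limits the precision of every value. The transgene could not be used to check the labels, since LecRK-VI.2 and the other 3 genes of its clade were not analysed here.

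The OH1 arrays stood apart from the Col-0 arrays. Pearson's r over log2 intensities lay between 0.992 and 0.995 within Col-0, between 0.976 and 0.984 within OH1, and between 0.927 and 0.955 across the genotypes. The leading principal component held 75.9% of the variance and separated the genotypes. The next one held 11.7% and set OH1 array 2 (score -41) apart from OH1 array 1 (score 34.4). The median SD of a probe set on the log2 scale was 0.139 in Col-0 and 0.181 in OH1.

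The receptor kinase gene AT1G35710 rose 33.5-fold (log2 change 5.07 ± 0.15 SE, n = 3 per group, adjusted p = 1.16e-05), from an intensity of 40.9 ± 4.33 (SD) to 1380 ± 211. The chitinase gene CHI (AT2G43570) rose 24.9-fold, from 111 ± 24.3 to 2830 ± 996, LUP5, which encodes a triterpene synthase, rose from 10.4 ± 1.59 to 214 ± 34.9, and the caffeoyl-CoA methyltransferase gene CCOAMT rose 18.1-fold. AT2G27420, a cysteine protease gene, fell by 5.13 ± 0.41 on the log2 scale, or 35.0-fold (adjusted p = 0.000282). GIS, a zinc finger regulator of trichome initiation, fell from 353 ± 4.85 to 39.3 ± 21.2, and TINY2, a DREB-type transcription factor gene, from 194 ± 30.1 to 21.8 ± 3.05.

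In total 7495 of the 22746 probe sets (33%) passed an adjusted p of 0.05 in limma, 3972 higher and 3523 lower in OH1. A change of at least 2-fold was met by 3004 of them (13.2%), 1924 higher and 1080 lower. All 3 OH1 arrays lay on one side of all 3 Col-0 arrays for 49.5% of the probe sets, where chance gives 10%. Of the probe sets that passed, 4028 name 1 gene, 145 name several and 3322 have no gene name in the annotation used here. The balance of directions moved with the scaling: 53% of the calls were higher as deposited, but 28.9% were higher when each array was centred on its median, and at 2-fold the share went from 64% to 45.8%. The median log2 change of all probe sets was -0.08 as deposited and -0.27 after that centring, so small changes are best read against these shifts. The number of calls was 4978 without Col-0 array 1 and 4785 without Col-0 array 3.

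**Figure D1:**
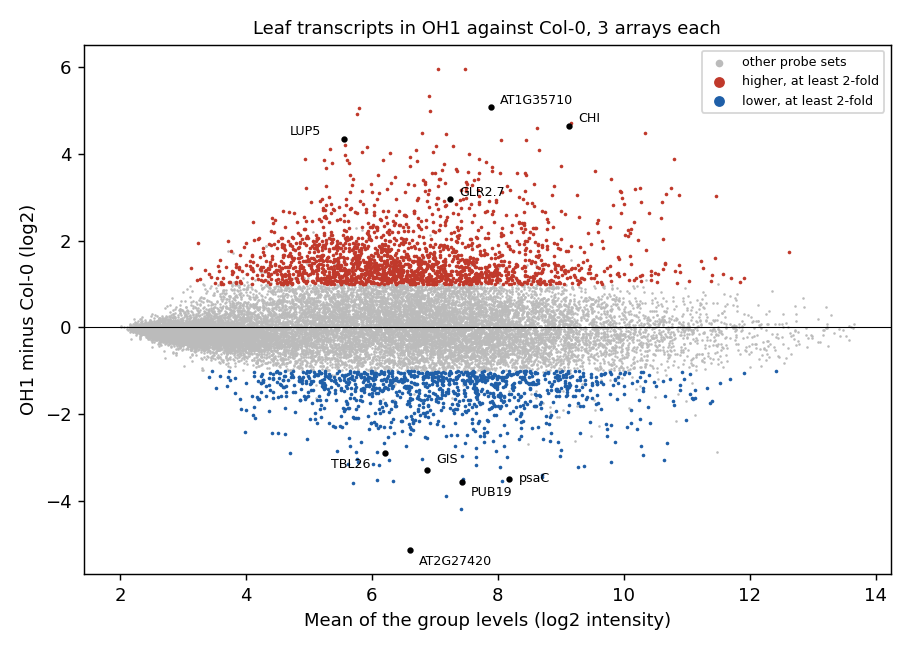
Change in OH1 against Col-0 (log2, vertical axis) for each of 22746 probe sets, plotted against the mean log2 intensity of the groups (horizontal axis), with named genes in black. Red points are the 1924 probe sets higher by at least 2-fold at an adjusted p below 0.05, and blue points the 1080 lower ones; AT1G35710 and AT2G27420 lie near the upper and lower ends.

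Among the other large rises, receptor kinase genes AT1G51890 and AT1G51860 rose 14.5-fold and 14.4-fold, the ankyrin repeat gene AT1G10340 rose 15.9-fold, and AT3G48080, a paralog of the immune regulator EDS1, rose 13.8-fold. The cell wall invertase family gene cwINV6 rose 16.3-fold. AT4G00700 and AT3G26470 rose 31.5-fold and 15.1-fold. AT3G28510 rose from 8.28 ± 1.53 to 375 ± 378, AT5G67340 from 9.67 ± 0.409 to 146 ± 56.9 and AT3G57950 from 10.7 ± 1.58 to 139 ± 35.7. The Col-0 levels of these 3 genes and of LUP5 lie close to the 5.6 to 8.2 of the bacterial TrpnX control probe sets, so their folds are uncertain. AT1G51860 (12.5 ± 1.17) and AT3G48080 (13 ± 4.41) started only slightly higher in Col-0, so the limit touches their folds too. It also touches folds given below for genes as dim in Col-0, such as GLR2.8 (12.3 ± 0.647), AT1G12290 (12.7 ± 1.49) and AT1G26420 (13.6 ± 2.3). The OH1 level of AT3G28510 also varied widely between arrays, as did that of AT2G44240 (761 ± 568). Among the largest falls of probe sets that name 1 gene, AT3G48460 dropped from 907 ± 48.3 to 78.3 ± 8.63. AT4G25780 dropped from 179 ± 34.9 to 14.9 ± 1.93 and AT5G41900 from 207 ± 9.27 to 23.3 ± 3.49. AT4G27657 and AT3G15310 had log2 changes of -4.19 ± 0.88 and -3.89 ± 0.68. AFR, an F-box gene of far-red light signalling, fell by 3.21 ± 0.69, and its adjusted p was 0.05 without Col-0 array 3.

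Loci associated with salicylic acid, a list compiled later from background knowledge, rose as a group. All 11 measured members of this list were higher in OH1, with a median log2 change of 3.05 and medians of 3.0, 2.87 and 3.37 on the 3 OH1 arrays. AT1G13470 rose 12.3-fold, AT3G47480 12.2-fold (68.9 ± 19.1 to 828 ± 161), AT3G48640 11.1-fold and SAL2 10.7-fold. The smallest log2 change of the list was 1.41, that of AT4G12490, picked out after its value was seen. Camera gave an adjusted p of 1.99e-10, and the adjusted p was 0.477 with an estimated correlation. Of the shorter list for salicylic acid and systemic resistance fixed beforehand, 3 genes were measured. SAG101, a partner of EDS1, rose 4.18-fold, from 15.0 ± 1.1 to 63.8 ± 14.9. GRX480 (log2 change 1.31, adjusted p = 0.0553) passed when adjusted over the list alone, where 2 of the 3 did, and UGT76B1 (1.02, adjusted p = 0.468) did not. The salicylic acid marker PR1 was not analysed here.

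Of 31 measured flagellin-responsive loci 15 rose, 2 fell and 14 did not pass, with a median log2 change of 0.87. Besides AT1G35710 and AT1G51890, AT2G18690 rose 5.55-fold (314 ± 58.3 to 1880 ± 899) and AT1G26420, of the berberine bridge enzyme family, 5.48-fold. AT3G55840 and AT4G36500, picked out after their values were seen, fell by 0.55 and 0.61 on the log2 scale. Camera gave an adjusted p of 3.64e-05, and the adjusted p was 0.666 with an estimated correlation. The median change on OH1 array 2 was 0.22, against 1.2 and 1.19 on the other arrays.

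The list of early genes of pattern-triggered immunity fixed beforehand did not shift. Of its 6 measured members 2 rose, also when adjusted over the list alone, and the camera adjusted p was 0.561. AT1G26380 rose 2.94-fold, from 31.1 ± 4.41 to 97.2 ± 40.2, and WRKY53 2.73-fold, from 114 ± 29.6 to 338 ± 175. The call of WRKY53 ended without any single array except OH1 array 2, with adjusted p between 0.0567 and 0.1. PUB22 (-0.63), PUB23 (-0.58), WRKY22 (-0.15) and STZ (0.11) did not pass, and FRK1 was not analysed here. The list's median of -0.02 and mean of 0.29 differ in sign. Both measured genes of the list of pattern receptors and early signalling rose. EFR, the receptor of bacterial elongation factor Tu, rose 2.59-fold (log2 change 1.37 ± 0.21), and BIK1, a cytoplasmic kinase downstream of pattern receptors, 2.19-fold (125 ± 4.51 to 275 ± 23.9).

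Among 6 measured WRKY transcription factor genes 4 rose and none fell, over all probe sets and adjusted over the list alone, with a median log2 change of 0.65. WRKY47 rose 4.97-fold, from 30.1 ± 3.43 to 150 ± 25.8. WRKY20 and WRKY6 rose 1.58-fold and 1.55-fold, calls that ended without at least 1 of the arrays (adjusted p between 0.0657 and 0.129 for WRKY20 without Col-0 array 1, Col-0 array 3, OH1 array 2 or OH1 array 3, and between 0.0537 and 0.0624 for WRKY6 without Col-0 array 2 or 3). With quantile normalization neither passed (0.0877 for WRKY20 and 0.0537 for WRKY6), and WRKY20 did not pass with arrays centred on the median (0.0875) or the 75th percentile (0.0595). WRKY53 is the other member that passed, with adjusted p up to 0.1 without single arrays. Camera gave an adjusted p of 0.0296 for the list, 0.0604 without Col-0 array 2, 0.0509 without dim probe sets, and 0.315 with an estimated correlation. NAC014, the one measured NAC gene, rose 1.69-fold.

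Of 24 measured genes in the list of TIR-type resistance genes 16 rose, none fell and 8 did not pass, with a median log2 change of 0.72. AT1G57630 rose 7.96-fold (64.1 ± 21.4 to 503 ± 133), AT2G32140 6.89-fold, AT1G72900 3.6-fold and AT3G44630 2.45-fold. Of 22 coiled-coil resistance genes 7 rose, none fell and 15 did not pass, the risen ones including AT1G12290 (4.24-fold), AT3G14470 (3.78-fold) and CW9 (2.36-fold). Camera gave adjusted p of 2.5e-08 for the TIR-type list and 0.00595 for the coiled-coil list, and the adjusted p was 0.425 for both with an estimated correlation. The coiled-coil median of 0.18 became -0.02 with median-centred arrays, and that list did not pass without dim probe sets (0.216).

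Receptor kinase families held some large rises among many genes that did not pass. Of 28 S-domain receptor kinase genes 8 rose and 1 fell, with SD1-29, AT2G19130 and AT1G61420 up 3.34-fold, 3.08-fold and 2.57-fold, and AT1G11410, picked out after its value was seen, down by 0.69 on the log2 scale. The camera adjusted p of 0.00934 became 0.425 with an estimated correlation, and 0.112 without dim probe sets, and the list median of 0.1 became -0.1 with median-centred arrays. Of 32 malectin-like receptor kinase genes 6 rose and none fell, AT5G59670 7.09-fold and AT1G51790 4.97-fold. The camera adjusted p of that list was 0.241 (median -0.03, mean 0.47), and it was 0.0346 after quantile normalization and 0.00132 without dim probe sets. Of 20 berberine bridge enzyme-like genes 6 rose and 2 fell, AT1G30700 6.01-fold, with a camera adjusted p of 0.167, which was 0.0161 without dim probe sets and 0.0142 without OH1 array 2. AT4G20820 (-0.63, with levels close to those of the TrpnX controls) and AT5G44410 (-1.22), picked out after their values were seen, were the ones that fell. Among 7 measured subtilase genes SBT3.5 rose 5.34-fold and SBT3.3 3.46-fold, and adjusted over the list alone 3 passed. The subtilase list had a camera adjusted p of 0.0749, which was 0.0325 after quantile normalization and 0.0453 without OH1 array 3.

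**Figure D2:**
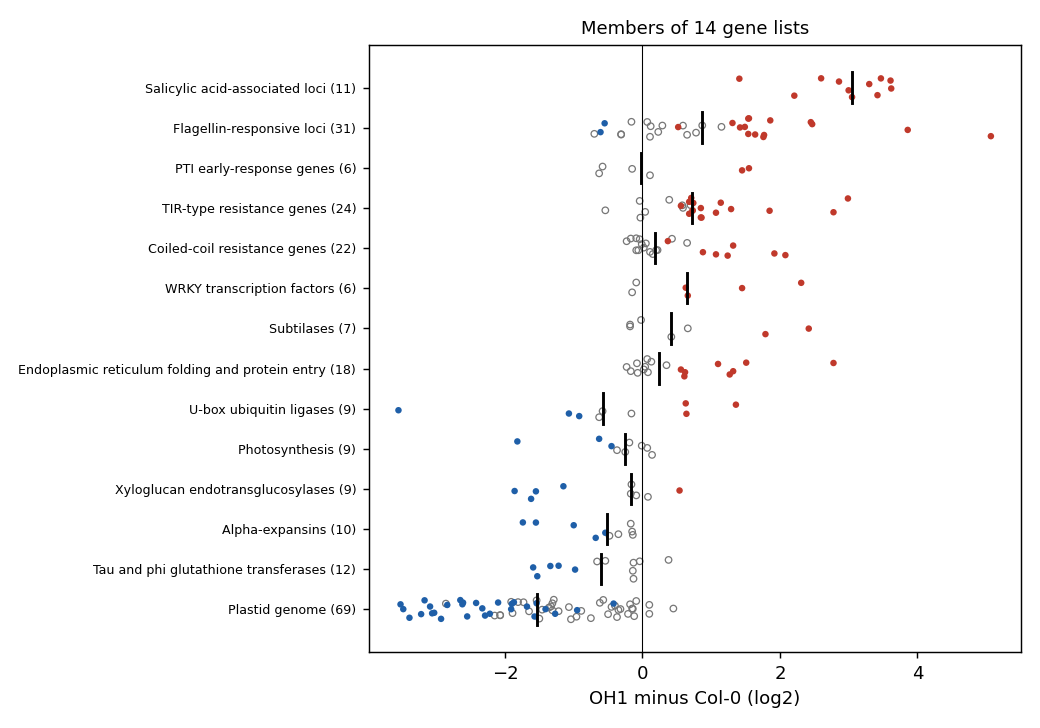
Change in OH1 against Col-0 (log2, horizontal axis) of each measured member of 14 gene lists (rows, number of members in brackets). Filled points passed an adjusted p of 0.05 over all probe sets (red higher, blue lower), open points did not, and the bar is the list median; medians run from 3.05 for salicylic acid-associated loci to -1.54 for the plastid genome, and that of the coiled-coil genes (0.18) turns to -0.02 with median-centred arrays.

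Both measured genes of jasmonate synthesis and response fell. JMT, which methylates jasmonic acid, fell by 2.4 ± 0.16 on the log2 scale, from 36.1 ± 0.696 to 6.93 ± 1.34. The OH1 level lies within the 5.6 to 8.2 of the TrpnX control probe sets, so the size of this fall is uncertain. THI2.1, a jasmonate-responsive thionin gene, fell by 0.39 from 10.6 ± 0.362 to 8.16 ± 0.943, close to that floor in both groups, and its call ended without any single array except OH1 array 2 (adjusted p between 0.0903 and 0.132) and with quantile normalization (0.133). PDF1.2, a defensin gene of the jasmonate and ethylene response, stood at 33.3 ± 2.94 in Col-0 and 35.7 ± 9.66 in OH1 (log2 change 0.07, adjusted p = 0.809), and the sign of this change turned with the scaling. Of 3 measured ethylene genes 1 rose and 2, PDF1.2 and PDF1.2b (0.53, adjusted p = 0.292), did not pass. EIN3, a transcription factor of ethylene signalling, rose 1.88-fold, with adjusted p of 0.0598 and 0.052 without Col-0 array 3 or 1. Of 4 measured genes of abscisic acid, dehydration and cold response, the cold-regulated gene COR15A fell by 2.24 ± 0.5 (535 ± 49.4 to 141 ± 111), with adjusted p of 0.0515 and 0.058 without Col-0 array 1 or 3. COR15B, COR47 and LTI30 (-0.43, 0.13 and 0.47) did not pass. In the later list of abscisic acid-induced loci 3 of 8 fell, namely PUB19, AT1G16850 and LEA4-5, with a camera adjusted p of 0.0961, or 0.0496 without OH1 array 1. PUB19, a U-box ubiquitin ligase gene, fell from 511 ± 5.69 to 58.2 ± 53.5. RD29A was not analysed here. Of 4 measured genes of auxin, brassinosteroid and cell expansion 2 rose and 1, EXPA8, fell, while IAA29 (0.9, adjusted p = 0.127) did not pass. GH3.3 and WES1, which encode auxin-conjugating enzymes, rose 4.8-fold and 3.01-fold.

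Genes of the secretory pathway and of ubiquitin ligases moved in part. In the endoplasmic reticulum, 8 of 18 folding and protein entry genes rose and none fell. AT4G16660, an HSP70 family gene, rose 6.86-fold (46.7 ± 22.2 to 306 ± 77.8), and AT5G07340, a calnexin family gene, 2.85-fold. The calreticulin gene CRT1b and the chaperone gene ATERDJ3B, both from the list fixed beforehand, rose 2.5-fold and 2.41-fold, calls that ended without OH1 array 3 or any one Col-0 array (adjusted p between 0.0568 and 0.0961 for CRT1b and between 0.0544 and 0.0714 for ATERDJ3B). The camera adjusted p was 0.0072, but 0.0743 without dim probe sets and 0.664 with an estimated correlation. Of 9 U-box ubiquitin ligase genes 3 rose and 3 fell, also when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.805). PUB43 rose 2.56-fold, PUB26 fell by 0.92 on the log2 scale, and PUB25 fell by 1.07 with adjusted p between 0.0575 and 0.151 without any single array except OH1 array 1.

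Of 10 alpha-expansin genes, which encode wall-loosening proteins, 5 fell, none rose and 5 did not pass, over all probe sets and adjusted over the list alone, with a median log2 change of -0.51. EXPA16 fell by 1.74 ± 0.22 on the log2 scale, EXPA8 from 678 ± 67.2 to 239 ± 82 and EXPA4 from 272 ± 21.5 to 138 ± 35.7, while EXPA20 fell by 0.68 on the log2 scale with an adjusted p of 0.0558 without Col-0 array 1. The remaining one was EXPA15, named after its value was seen. Of 12 tau and phi glutathione transferase genes 5 fell, none rose and 7 did not pass, and 6 fell when adjusted over the list alone. GSTU18 fell from 953 ± 34.1 to 382 ± 72.6, GSTU20 from 1430 ± 91.4 to 726 ± 36.5, GSTU23 from 40.7 ± 5.16 to 13.7 ± 3.12 and GSTU28 and GSTF4 by 1.53 and 1.22 on the log2 scale. Camera gave an adjusted p of 0.0154 for each of these lists, and with an estimated correlation the adjusted p was 0.315 for the expansins and 0.306 for the transferases. Of 9 xyloglucan endotransglucosylase genes 4 fell and 1 rose, also when adjusted over the list alone. XTH32 fell from 1090 ± 91 to 383 ± 104, XTH19, XTH18 and XTH33 by 1.86, 1.62 and 1.15 on the log2 scale, and XTH29, picked out after its value was seen, rose by 0.54 from a level close to that of the TrpnX controls. The camera adjusted p of that list was 0.167, and it was 0.0464 without OH1 array 1 and 0.0432 without dim probe sets.

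Nuclear genes of photosynthesis fell in part. Of 9 measured members 3 fell and none rose, over all probe sets and adjusted over the list alone, with a median log2 change of -0.25 and a camera adjusted p of 0.113. LHCB4.3, a light-harvesting antenna gene, fell by 1.82 ± 0.14 on the log2 scale (334 ± 17.9 to 95.3 ± 14.2), and SBPASE, an enzyme of the Calvin cycle, fell by 0.63 (3930 ± 240 to 2550 ± 153). PSAN, a photosystem I subunit gene, fell by 0.45, with adjusted p between 0.0574 and 0.0942 without any single array except OH1 array 2. In the later and overlapping list of chloroplast electron transport and Calvin cycle genes, 6 of 17 fell and 1 rose (camera adjusted p = 0.0701, and 0.037 without Col-0 array 3, 0.0261 without OH1 array 2 or 0.0374 after adding 32), and NdhL fell from 877 ± 53.5 to 345 ± 55.9. Of 10 chlorophyll and haem synthesis genes 2 fell, or 1 when adjusted over the list alone. CHLM fell from 3140 ± 39.2 to 1890 ± 245, and CHLI2 fell by 0.66 on the log2 scale with adjusted p between 0.0987 and 0.138 without any single array except OH1 array 2, and 0.0558 with quantile normalization.

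Of 69 measured genes of the plastid genome itself 29 fell, none rose and 40 did not pass, with a median log2 change of -1.54. The medians of OH1 arrays 1, 2 and 3 were -1.54, -0.29 and -2.91. The photosystem genes psbT and psaC fell from 203 ± 19 to 22.6 ± 17.8 and from 853 ± 20.4 to 98.9 ± 78.1, psbB 9.32-fold, and ndhE from 546 ± 64.1 to 74.2 ± 45. The photosystem I gene psaI fell by 3.39 ± 0.8 on the log2 scale, with adjusted p of 0.0632 and 0.0607 without Col-0 array 1 or 3. Camera gave an adjusted p of 5.11e-07, and the adjusted p was 0.727 with an estimated correlation. A control probe set for 25S ribosomal RNA was also lower, by deviations of -1.1, -0.57 and -1.37 on the 3 OH1 arrays. The 24 probe sets for poly-A control transcripts had medians of -0.52, -0.1 and -0.7 on the same arrays. The 18 probe sets for hybridisation controls had medians of 0.17, -0.74 and 0.94, against at most 0.16 on a Col-0 array, in the reverse order of the plastid medians.

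**Figure D3:**
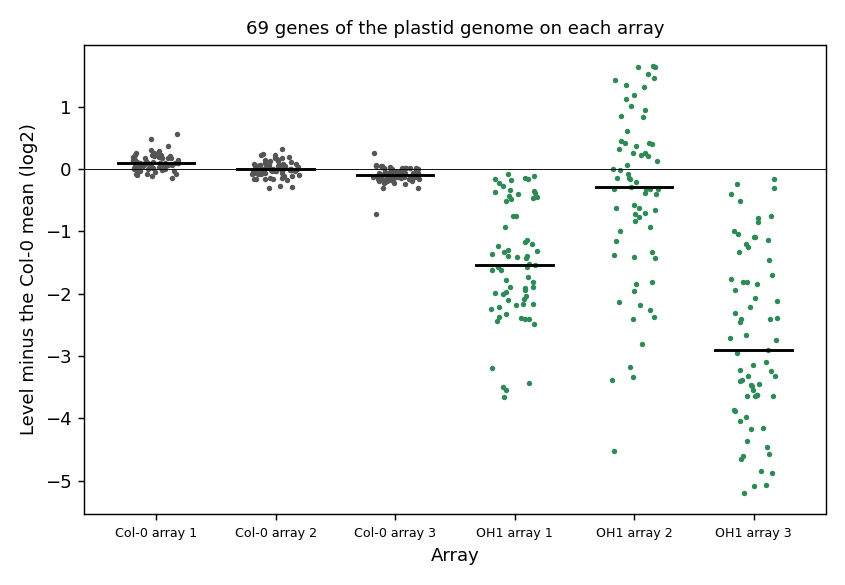
Level of each of 69 plastid genes on each array, as the log2 deviation from its Col-0 mean (vertical axis), with black bars at the array medians. OH1 arrays 1 and 3 have medians of -1.54 and -2.91, while OH1 array 2 has a median of -0.29, with values from -4.52 to 1.65.

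The balance of 3' and 5' control probe sets, a sign of RNA integrity, was computed on 1 pair per transcript. For actin the log2 ratio was 1.11 ± 0.07 in Col-0 and 1.11 ± 0.08 in OH1. It was close between the groups for GAPDH (0.65 ± 0.13 and 0.79 ± 0.12) and higher in OH1 for ubiquitin (0.68 ± 0.03 and 0.89 ± 0.13). On the other pairs the 3' probe set rose more than the 5' one. The log2 changes were 0.43 against -0.01 for actin, 0.77 against 0.47 for ubiquitin and 0.74 against 0.62 for GAPDH. Equal RNA integrity in the groups is therefore not shown. Markers of other organs and cell types were measured for few genes. The root marker EXPA7 (-0.48, adjusted p = 0.093), the floral regulator AGL24 (-0.73, adjusted p = 0.068), the stomatal regulators SPCH, FMA and MUTE (-0.16, -0.12 and -0.07), the phloem sugar transporter gene SWEET11 (-0.11) and the replication gene PRL (0.89, adjusted p = 0.12) did not pass. AGL24 passed with quantile normalization (-0.88, adjusted p = 0.0346), arrays centred on the median (0.0223) or the 75th percentile (0.0377), array weights (0.0497), the replicate block (0.0304) and without OH1 array 3 (0.0496), and EXPA7 passed with median-centred arrays (-0.68, adjusted p = 0.0287). FMA had a log2 change of 0 without OH1 array 1, and PRL passed without that array (1.35, adjusted p = 0.00453) and with array weights (0.0419). SWEET11 passed without OH1 array 1 (-0.48, adjusted p = 0.0209) and turned to 0.08 and 0.07 without OH1 array 2 or 3. In lists compiled later, 1 of 4 stomatal genes fell and the 3 named above did not pass. That gene, STOMAGEN, a mesophyll signal that promotes stomata, fell from 481 ± 35.5 to 173 ± 64.6. WSD1 of wax ester synthesis fell by 1.6 on the log2 scale to 10.3 ± 1.29, close to the TrpnX level, and AT5G33370, the other measured wax and cutin gene, fell by 0.76. Of 5 secondary wall genes 2 fell and 3 did not pass. The xylan genes IRX15-L and IRX15 fell by 1.2 and 0.43, the latter with adjusted p between 0.0654 and 0.129 without any single array except OH1 array 2. None of 15 pollen and anther genes passed, but with median-centred arrays AT1G66850 (-0.58, adjusted p = 0.00869) and AT3G62710 (-0.7, adjusted p = 0.0204) did. Both also passed with arrays centred on the 75th percentile (0.03 and 0.0493), and AT1G66850 with an intensity trend (0.0255). The levels of AT1G66850, 10.2 ± 1.18 in Col-0 and 7.84 ± 0.297 in OH1, lie close to the TrpnX level. Of 6 root hair genes 1 fell and 5 did not pass, and none fell when adjusted over the list alone. That gene, AT3G54580, fell by 0.56, with adjusted p between 0.0839 and 0.115 without Col-0 array 2 or 3 or OH1 array 1 or 3.

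The reference genes PEX4 (-0.36, adjusted p = 0.0808), AT4G34270 (0.15, adjusted p = 0.329) and AT2G28390 (-0.06, adjusted p = 0.782) did not pass. With median-centred arrays PEX4 passed (-0.56, adjusted p = 0.0146), as it did with arrays centred on the 75th percentile (0.0358), and AT4G34270 turned to -0.05. GI, a clock gene, rose 5.01-fold from 33.9 ± 3.17 to 268 ± 298, with log2 deviations of 0.81, 4.17 and 1.99 on the OH1 arrays and adjusted p between 0.076 and 0.135 without OH1 array 3 or any one Col-0 array, and 0.0629 with quantile normalization. Another clock-regulated gene, CCL, rose 10.8-fold, from 254 ± 52.4 to 3130 ± 2190, and these were the 2 of 6 clock output loci that passed. The transcription factor gene WRKY6, also listed under senescence, rose 1.55-fold (adjusted p up to 0.0624 without Col-0 array 2 or 3), while SAG29 (-0.15) did not pass. UGT74B1 of indole glucosinolate synthesis (0.55), BCAT4 and AT2G31790 of aliphatic glucosinolate synthesis (-0.23 and -0.33) and the heat shock genes ATHSP22.0 and AT1G53540 (-0.33 and 0.17) did not pass. With median-centred arrays BCAT4 (-0.42, adjusted p = 0.0237) and AT2G31790 (-0.53, adjusted p = 0.0369) passed and AT1G53540 turned to -0.03, as it did without OH1 array 3. Of 4 flavonoid and anthocyanin genes 1 fell, and UF3GT (-0.39), DFR (-0.23) and AT5MAT (0.02) did not pass. The anthocyanin glucosyltransferase gene AT4G14090 fell by 0.52 on the log2 scale, with adjusted p between 0.0558 and 0.0943 without Col-0 array 1 or 3 or OH1 array 1 or 3.

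The measured genes next to the LecRK-VI.2 locus in the reference assembly TAIR10.1 were TAAC and LHCB4.1 on one side and AT5G01610 and TBL35 on the other. TAAC (0.4, adjusted p = 0.173) and LHCB4.1 (-0.01, adjusted p = 0.954; 9500 ± 341 in Col-0 and 9470 ± 1160 in OH1) did not pass, and LHCB4.1 changed sign without Col-0 array 2 (0.02) or OH1 array 3 (0.09). AT5G01610 rose 2.63-fold, from 41.5 ± 9.57 to 108 ± 17.3. TBL35 fell by 0.55 on the log2 scale, with adjusted p between 0.0505 and 0.0715 without OH1 array 2 or any one Col-0 array.

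Of 55 class III peroxidase genes 4 rose and 9 fell, or 3 and 6 when adjusted over the list alone, with AT5G64120 and AT5G64110 up by 2.23 and 1.63 on the log2 scale and AT3G28200 at -1.2 (camera adjusted p = 0.372). Of 115 cytosolic ribosomal protein genes 2 rose and 9 fell (0.788), or 1 and 3 when adjusted over the list alone. Of 14 small heat shock and chaperone genes 1 rose, AT5G48570 by 2.68 (adjusted p = 0.0614 after adding 32), and 3 fell (0.788). Of 10 nitrate-responsive loci 2 rose and 2 fell (0.797), of 9 loci induced by dark and sugar starvation 2 rose and 1 fell (0.222, and 0.0334 without OH1 array 3), and the sulfur starvation loci AT1G04770 (0.28) and BGLU28 (0.09, and -0.11 with median-centred arrays) did not pass. BGLU28 stood at 6.96 ± 0.377 in Col-0 and 7.41 ± 0.508 in OH1, within the range of the TrpnX controls.

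Among the 8 lists fixed beforehand that had at least 5 measured members, 1 shifted higher and 2 lower in camera. With a correlation estimated for each list none passed, and 1 had an unadjusted p below 0.05. Among the 63 lists compiled later, 10 shifted higher and 5 lower, none passed with an estimated correlation, and 5 had an unadjusted p below 0.05. Fry, which tests whether a list's genes move on balance one way and compares it with no other genes, passed 5 of the 8 and 30 of the 63.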

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

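All tests in this part were chosen after the results were seen. The control probe sets for 3 plant transcripts, which the comparison leaves out, were higher in OH1 than in Col-0. The median log2 difference was 0.75 for ubiquitin (5 of 5 probe sets with the groups fully apart), 0.62 for actin (5 of 6) and 0.55 for GAPDH (5 of 5). Array scaling alone accounts poorly for this. The lowest of these medians over 4 scalings, the deposited one included, was 0.35, above the 0.2 by which a Col-0 array deviated at most. A changed balance of 3' and 5' ends as the only cause is also argued against. The median over the 10 probe sets at the 5' end and the middle was 0.56 (lowest -0.01, highest 1.05). The balance itself was not equal on every pair. The 3' and 5' probe sets changed by 0.75 and 0.54 in a ubiquitin pair. In the actin pairs they changed by 0.43 and -0.01 and by 0.67 and 0.67. A part played by the balance therefore stays open. The poly-A control transcripts did not rise along with them, with a median log2 difference of -0.44 (6 of 24 probe sets fully apart lower, 0 higher). Their medians were -0.52, -0.1 and -0.7 on the OH1 arrays, against 0.14, -0.19 and 0.06 on the Col-0 arrays. These values give no sign of a yield higher in OH1 for all transcripts. A labelling yield that differs between transcripts was not tested and stays open. A difference in these plant transcripts between the plants stays open as well.

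The median log2 change of the salicylic acid-associated loci was 3.05 as deposited and 3.04, 2.85 and 2.97 under the 3 other scalings. The array medians ran only from 5.396 to 5.648 on the log2 scale. A shift common to all probe sets of an array was thus too small to give this rise. For the same reason the result of these scalings was largely fixed in advance. A different time of harvest could raise such genes along with clock genes. The list median varied by 0.5 over the OH1 arrays while GI varied by 3.36, and the arrays differed in order. The salicylic acid list fixed beforehand, with 3 measured genes, was less steady, with medians of 1.12, 0.4 and 2.41 on OH1 arrays 1, 2 and 3. Harvest time and genotype cannot be told apart because nothing used here records the time for either group. The genotype remains among the open explanations, as a hypothesis.

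The median log2 change of the plastid transcripts was -1.54 as deposited and -1.59, -1.74 and -1.61 under the 3 other scalings. The array medians were too close for a shift common to an array to give this fall, so these scalings could change it little. A loss of plastid RNA by 1 common factor is argued against. Over the 55 plastid genes above an intensity of 100, the SD of log2 deviations was 0.96, 1.47 and 1.32 on the OH1 arrays, and the smallest was 8.53 times the largest of a Col-0 array. An uneven yield of transcripts with short or no poly-A tails could not be decided, because mitochondrial transcripts, with a median log2 change of -0.14 over 11 genes (3 lower, 0 higher) and medians of -0.04, -0.21 and -0.27 on the OH1 arrays, were dim (median Col-0 intensity 22.6). Such an uneven yield, and a difference between the plants in plastid transcripts, may each account for the fall, with the lower 25S ribosomal RNA signal beside it.

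With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The genotype split called 7495 probe sets in limma and 3004 at 2-fold (1 of 10 splits gave as many in each case). The highest other split called 0, with 650 probe sets at an unadjusted p below 0.05. All other splits mix the genotypes within each group, which widens the spread there and holds their calls down. The contrast of these counts therefore does not measure chance. For the lists fixed beforehand, 3 of the 10 splits gave as many shifted lists as the genotype split, the value being 3 in both it and the highest other. For the later lists 1 split, the genotype split, gave 15, and the highest other gave 13. Every other split shares the genotypes unevenly between its groups, so part of the genotype difference remains and can shift lists. The list counts of these splits therefore give no chance level either.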

How the results depend on the processing

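The alternatives were planned before the data were examined. Of 176 named genes 131 kept their direction and their side of the threshold under all alternatives run for them, and of 2620 values 2443 did so, 144 lost the call, 19 gained one and 14 changed sign. Most of the named genes were chosen for a call and a large change in these same arrays. Their stability was therefore partly built in and does not stand for all probe sets. No called probe set shared with the reported fit changed direction under any other scaling, variance model, offset or left-out array. The reversals were all in uncalled genes. PDF1.2 turned to -0.07 with quantile normalization, -0.13 with median centring, -0.01 with centring on the 75th percentile, 0 with array weights and -0.14 without OH1 array 1. Median centring turned AT1G53540 (-0.03), AT4G34270 (-0.05) and BGLU28 (-0.11). Without single arrays PDF1.2 ran from -0.14 to 0.18, AT1G53540 from -0.03 to 0.28, LHCB4.1 from -0.07 to 0.09, FMA from -0.28 to 0 and SWEET11 from -0.48 to 0.08. The cause of these turns was not tested.

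Median centring raised the lower calls to 7547, and to 1678 at 2-fold. Adding 32 before the log, which shrinks changes of dim probe sets, left 1475 changes of at least 2-fold (918 higher, 557 lower). At an adjusted p of 0.01 there were 4145 calls (2373 higher, 1772 lower), and at 1.5-fold 5884 (3365 higher, 2519 lower). With 1 probe set per gene, and so fewer tests, there were 3983 calls (1946 higher, 2037 lower) and 1494 at 2-fold (900 higher, 594 lower). Without single arrays the calls ran from 4785 to 7747 and the lower calls from 2133 to 3686.

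With an estimated correlation 0 of 8 and 0 of 63 lists passed, with adjusted p of 0.315 (WRKY and alpha-expansins), 0.306 (glutathione transferases), 0.666 (flagellin), 0.477 (salicylic acid), 0.425 (TIR-type) and 0.727 (plastid). Fry passed 5 of 8 and 30 of 63, among them photosynthesis (0.00954) and subtilases (0.00246), and not the plastid genome (0.0854). Without dim probe sets WRKY was at 0.0509 and the xyloglucan endotransglucosylases at 0.0432, and quantile normalization gave the subtilases 0.0325. Without single arrays the adjusted p of WRKY ran from 0.0139 to 0.0604, of the xyloglucan endotransglucosylases from 0.0464 to 0.256 and of the subtilases from 0.0453 to 0.123.

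The replicate numbers did not pair the arrays, as deviations of arrays with the same number correlated between -0.03 and 0.06. With the replicate block limma called 6966 probe sets, 6617 of them shared with the reported calls. No alternative was run for the LecRK-VI.2 level, or for lists without the clade VI genes, since these genes were not analysed here, and robust eBayes was not run on lists.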

Other observations

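The tests of gene order in the nucleus were written before their results were seen, and that of plastid gene order after. Some families recognised by symbol alone shifted in camera at the preset correlation. Of 22 TBL genes, a family named for the cell wall acetylation mutant trichome birefringence, 13 fell, 2 rose and 7 did not pass. TBL26 fell from 202 ± 27.3 to 27.1 ± 4.63, TBL28 and TBL45 by 1.54 and 1.5 on the log2 scale, and TBL32 and TBL18, picked out after their values were seen, rose by 0.51 and 0.5. Of 11 RALFL genes, which encode small secreted peptides, 5 fell, none rose and 6 did not pass, with RALFL24 from 362 ± 51 to 106 ± 13.8 and RALFL22 from 599 ± 34.5 to 190 ± 96.3. Of 14 SWEET sugar transporter genes 4 fell, none rose and 10 did not pass, SWEET2 from 999 ± 127 to 211 ± 120 and SWEET17 from 391 ± 30.9 to 165 ± 73.9. Camera gave adjusted p of 0.00113, 0.00595 and 0.0281 for these families. With an estimated correlation the adjusted p was 0.425, 0.425 and 0.477, and the SWEET family did not pass with median-centred arrays (0.077) or without dim probe sets (0.145).

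Families of protein turnover, secretion and ion channels shifted the other way in part. Of 12 UBP genes for ubiquitin-specific proteases 6 rose, none fell and 6 did not pass, with UBP23 up 2.96-fold, UBP15 2.68-fold and UBP18 2.05-fold. Of 8 ATG autophagy genes 4 rose, none fell and 4 did not pass, ATG8E 3.68-fold and ATG8B 2.41-fold. Of 7 GLR genes for glutamate receptor-like channels 4 rose, none fell and 3 did not pass, GLR2.7 7.73-fold (53.7 ± 5.08 to 426 ± 114), GLR2.8 5.84-fold and GLR1.4 5.31-fold. Of 9 genes whose symbol begins with SEC 6 rose, none fell and 3 did not pass. SEC15A, of the exocyst that tethers secretory vesicles, rose 1.9-fold and SEC1B 2.38-fold, and SEC itself, up 1.88-fold, is a glycosyltransferase gene outside this theme. Camera gave adjusted p of 0.000142, 0.00934, 0.00778 and 0.000875 for UBP, ATG, GLR and SEC, and with an estimated correlation 0.477, 0.655, 0.477 and 0.477. The ATG and GLR families did not pass without dim probe sets (0.0743 and 0.054).

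A hypothesis was that genes higher in OH1 lie next to each other. Along the 5 nuclear chromosomes 13217 genes were ordered by the reference, and 904 of them rose at least 2-fold. These formed 90 neighbouring pairs, against 61.8 on average with a central range of 48 to 77, in 10000 shuffles of the order (one-sided permutation p = 0.0004). The 576 genes that fell formed 33 pairs, within the 16 to 35 of shuffled orders (one-sided permutation p = 0.06). A run of 4 measured neighbours rose together at AT4G39670, AT4G39675, AT4G39680 and AT4G39690, and another at AT5G45430, AT5G45480, AT5G45500 and AT5G45510, all named after their values were seen. Probe sets shared by related genes may produce such pairs. Leaving out probe sets marked as shared gave 89 pairs, but it removed only 2 of the 904 genes and decides nothing.

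Another hypothesis was that neighbouring genes on the plastid genome change alike. The mean absolute difference in log2 change between neighbours was 0.85 over 69 genes, below the 1.02 to 1.36 of 10000 shuffled orders (one-sided permutation p = 0.0001, the smallest these shuffles can give). On OH1 array 2, 27 of the 69 genes lay above their Col-0 mean and on the other OH1 arrays none did. This would be consistent with shared transcripts of plastid operons, and overlap of the probes was not tested.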
